A study of Arabidopsis thaliana with 24 samples.

How the data were processed

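Per the labels' protocols, plants grew in a chamber with 16 h light and 8 h dark at 21 degrees by day and 18 degrees by night, DNA was prepared from rosette leaves with a column kit, and it was labelled with biotin by random priming. Per the series' design text, 3 arrays were hybridized for each of 8 accessions, in a pair of balanced batches that the labels do not assign to arrays. The submitters' processing notes name MAS5 and RMA, which are array summarization methods, without giving their role or order. The genome build and the source of the gene-based probe grouping are not given in the sources used here.

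The authors deposited 1 table with a line per probe, which gives the probe set, the probe's number within it, the number of probes of the set, and 24 columns of array values. The 24 value columns are named by array codes that match no title, description or other label, and they were left out of every step. The codes form runs of 3 or 6 consecutive numbers, which fit 3 arrays per accession, but neither code order nor values were used in place of a label to say which array is which accession. The other number of the deposited table, the number of probes per probe set, is a property of the probe set and of no sample. As a count it was used as given, and how probes were grouped or chosen for each set is not stated. It equalled the number of lines in all 21441 probe sets. Because the value columns were not used, the depth and precision of the hybridizations are unknown here.

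The comparisons fixed before the data were examined were limma models of the probe and probe-set signals across the 8 accessions, permutation tests of organelle signal and runs of neighbouring genes. None could be run without a match of columns to samples. The rule for named genes ranked genes by their signal differences and could not be applied, except that FRI and FLC were to be named whatever their values. The other genes are named as members of 5 gene lists fixed in advance, picked after their probe numbers were seen, and the remaining names (the largest probe sets) were also picked after the values were seen. Lists defined by gene descriptions were not used, since no description was given with the gene names.

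Probe sets were matched to the TAIR10.1 RefSeq gene table by locus code. Of the 21441 probe sets 21200 matched and 241 did not, of which 77 are mitochondrial and 3 chloroplast loci and 161 are nuclear. The table's build is not stated, so the reference served for gene symbols, gene classes and which genes neighbour each other, and no coordinates are given. An item of the gene lists is not reported here by name. A gene is called not analysed here when its locus code has no probe set in the table as used, which does not tell why.

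Shares of genes with a probe set, and shares of genes with fewer than 11 probes, were compared with those of all other nuclear protein-coding genes by two-sided Fisher's exact tests in SciPy 1.17.1 (Python 3.11.15, pandas 2.3.3, NumPy 2.4.6), with Benjamini-Hochberg adjustment over the lists or chromosomes and a threshold of 0.05. Intervals are exact Clopper-Pearson intervals at 95%. These tests replaced the planned ones after the table had been seen. The list test was tested on simulated data over the 27444 genes: of 100 lists of 35 genes drawn at a background share of 75%, 6 were called at an unadjusted 0.05, and of 100 drawn at 30% all 100 were called. The simulation did not show whether smaller differences, or shares above the background, would be called. The difference between chromosomes was also set against all 27444 shifts of the genes' status along the gene order of the reference. Alternatives tried were a minimum of 5 or 11 probes per gene and all nuclear loci as the background.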

Results

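The series hybridized genomic DNA from rosette leaves of Arabidopsis thaliana to the ATH1 array, a single-channel oligonucleotide array whose short probes were designed on the Columbia reference strain. Genomic DNA in place of RNA makes each probe a test of the DNA itself, since a probe binds less well where an accession carries a mismatch or lacks the sequence. The samples fall into 8 groups, the accessions C24, Ag0, Bil5, Eden1, Got22, Omo2_3, Tamm2 and Ull2_5, with 3 arrays in each group and 24 arrays in all. The series title describes all 8 as winter annuals, plants that germinate in autumn and flower after winter. The labels state that sequence polymorphism was the object of the study, so the design implies a comparison of probe signal among the 8 accessions.

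The hybridization signals were not analysed here. The 24 columns of array values carry codes that occur in no label of any sample, so no column was assigned to an accession, and no difference between accessions is reported. What the table shows without those columns is which genes the comparison covered and with how many probes. These numbers belong to the deposited grouping of probes, whose source is not given, and to no sample, so they have no replicates. The gene numbers below are complete counts of that grouping. The exact binomial intervals treat genes as independent draws, which they are not, and describe no variation between samples.

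Most nuclear genes of the plant were represented in the table. It held 219849 probes in 21441 probe sets, each named by a gene locus, of which 21361 were nuclear. Of the 27444 nuclear protein-coding genes in the TAIR10.1 reference annotation, 20345 (74.1%) had a probe set. Of 3917 nuclear loci annotated as pseudogenes, 735 (18.8%) had one, as did 111 of 926 transcribed pseudogenes (12.0%) and 3 of 3480 long non-coding RNA loci (0.0862%). The share of protein-coding genes with a probe set was lowest on chromosome 4, at 71.9% (95% exact interval 70.5 to 73.3), against 74.5% for the other 4 chromosomes together. This difference passed a two-sided Fisher's exact test that takes genes as independent, after Benjamini-Hochberg adjustment over the 5 chromosomes (adjusted p = 0.0024). However, among neighbouring genes of named families, missing probe sets went together more often than their base rate. Neighbours without such names were not examined. A rotation test shifts the genes' status along the gene order and so keeps neighbours together. The chromosome 4 difference did not pass it (two-sided rotation test, 27444 shifts, adjusted p = 0.972). The shifts overlap heavily, since chromosome 4 alone spans 4180 of the 27444 genes, so they are far from independent. The rotation test therefore had little power for a whole chromosome and does not decide whether chromosome 4 differs. The other chromosomes lay between 73.9% (chromosome 2) and 75.1% (chromosome 5), and none of them passed either test (adjusted p from 0.119 to 0.945 by Fisher's exact test, and 0.972 for each by rotation).

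Organelle DNA, abundant in leaf preparations, was represented unevenly. The mitochondrial genome had 77 probe sets with 798 probes. The chloroplast genome had 3 probe sets with 14 probes.

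The number of probes differed between genes. The median was 11 probes per gene, and 11435 probe sets (53.3%) had exactly 11. Another 9763 (45.5%) had fewer, down to 3, and 243 (1.13%) had more. The largest sets were those of ACT7, an actin gene, with 83 probes, and of GAPC1, a cytosolic glyceraldehyde-3-phosphate dehydrogenase of glycolysis, with 67 probes. The only other sets above 30 probes were those of AT2G07682, which has no symbol in the reference, with 33, and of SUVR5, named for its similarity to the Su(var)3-9 chromatin regulators, with 31.

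Genes of flowering time, the trait that separates winter annuals from rapid cyclers, were mostly covered. Of 35 such genes on a list fixed in advance, 29 (82.9%, interval 66.4 to 93.4) had a probe set. FRI, which raises FLC expression and is a main determinant of the winter annual habit, had 11 probes. FLC, the repressor of flowering that vernalization silences, had 10. Among the relatives of FLC, FLM (MAF1 in the reference) had 20 probes, MAF4 had 8 and MAF5 had 7, while MAF2 and MAF3 were not analysed here. The floral integrators FT and TSF had 11 probes each, SOC1 (AGL20 in the reference) had 8, and CO, the photoperiod regulator, had 10. Of the vernalization genes, VRN1 had 10 probes, VRN2 had 7 and VIL1 (VRN5 in the reference) had 11, and VIN3 was not analysed here. Of the autonomous pathway genes, FY, FLD and LD had 11 probes each, FCA had 6, and FVE and FPA were not analysed here. FES1 was the remaining gene of this list that was not analysed here. The phytochrome genes PHYA, PHYB and PHYC had 11 probes each and PHYD had 10.

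Disease resistance genes of the nucleotide-binding leucine-rich repeat class, several of which lie in clusters of similar copies, were covered at the same share, 29 of 35 (82.9%, interval 66.4 to 93.4). RPM1, RPS2 and RPS4, receptors that recognize bacterial effectors, had 11 probes each, and RRS1 had 21 and RPS6 20. In the cluster of RPP4, RPP5 and SNC1 the numbers differed, with 11 probes for RPP4, 8 for SNC1 and 3 for RPP5. RPP1, one of its relatives (AT3G44670), RPP7, RPP8, NRG1.1 and NRG1.2 were not analysed here.

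The 28 genes of glucosinolate metabolism, which makes and breaks down the mustard oil compounds that deter herbivores, had probe sets for 24 (85.7%, interval 67.3 to 96.0). AOP1, AOP2 and AOP3, neighbouring genes of side-chain modification, had 10 probes each, and AOP2 is annotated as a transcribed pseudogene in the reference. MAM1 had 9 probes and MAM3 (IMS2 in the reference) had 8, both genes of side-chain elongation. The myrosinase genes TGG1 and TGG2 and the paired cytochrome P450 genes CYP79F1 and CYP79F2 were not analysed here.

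Cold, drought and abscisic acid response genes were represented for 25 of 28 (89.3%, interval 71.8 to 97.7). The neighbouring cold regulators CBF1, CBF2 and CBF3 (DREB1A in the reference) and the related CBF4 had 11 probes each, as did ICE1, COR15A and COR15B. ERECTA (ER in the reference), a receptor kinase gene, had 10. KIN1, KIN2 and P5CS1 were not analysed here. Of 19 housekeeping genes, taken as a conserved comparison group, 16 (84.2%, interval 60.4 to 96.6) had a probe set, and UBQ5, UBC9 and the elongation factor gene EF1A (AT5G60390) were not analysed here.

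**Figure D1:**
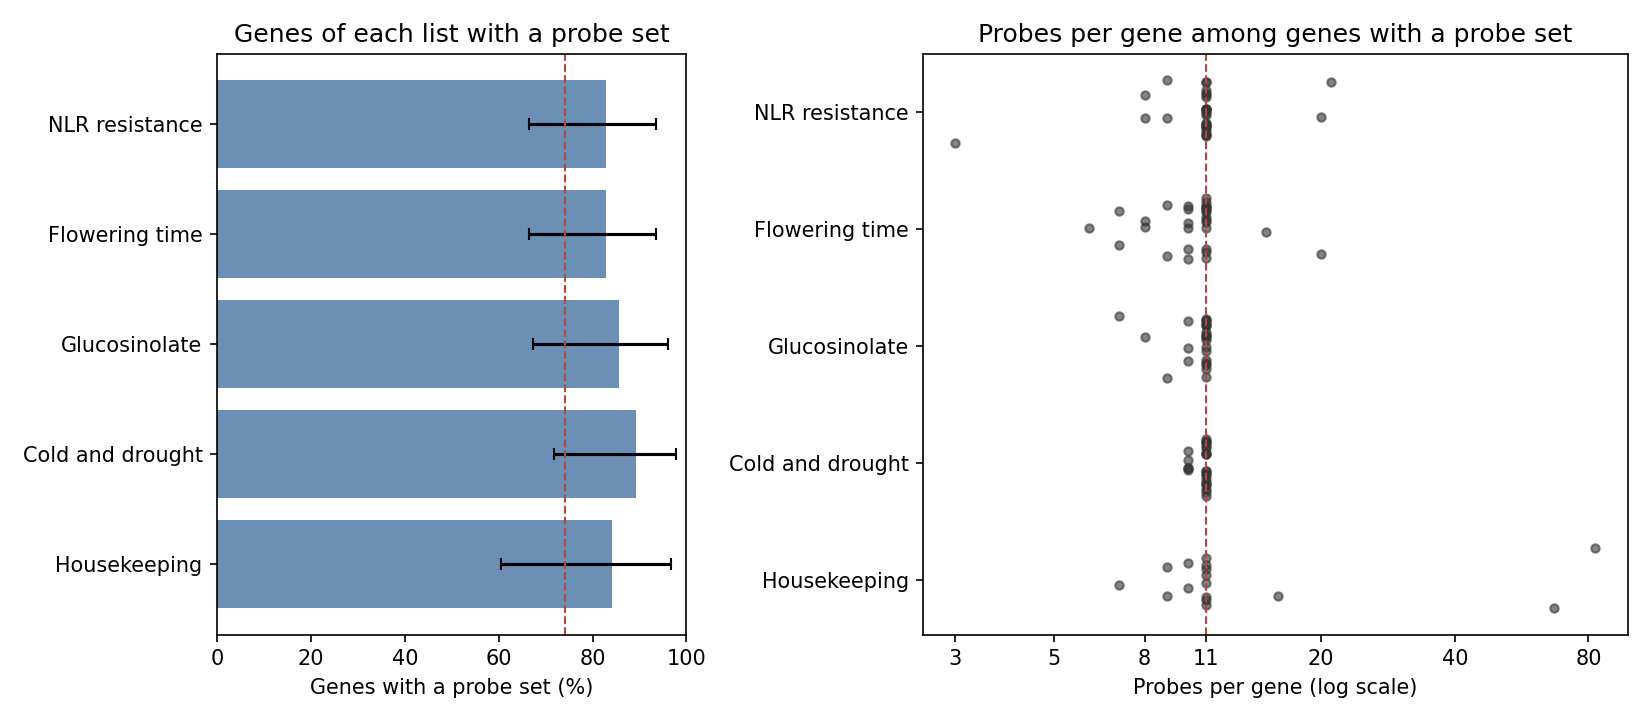
Left, the percentage of genes of each fixed list with a probe set, with 95% exact binomial intervals as bars and a dashed line at the 74.1% of all nuclear protein-coding genes; every interval includes that line. Right, the number of probes of each gene with a probe set, 1 point per gene (vertical spread within a list carries no value), on a log axis with a dashed line at 11; RPP5 is lowest at 3 probes, and GAPC1 and ACT7 are highest at 67 and 83.

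None of the 5 lists passed the threshold for a difference from the other nuclear protein-coding genes in its share with a probe set, by a two-sided Fisher's exact test adjusted over the lists. The adjusted p ranged from 0.413 for the cold and drought list to 0.435 for the housekeeping list. This result is for genes counted as covered whatever the size of their probe set. It changed when only genes with 11 or more probes were counted. The share was then higher than in the other genes for resistance genes (odds ratio 3.16, Fisher's exact test, adjusted p = 0.00391), cold and drought genes (3.62, adjusted p = 0.00391) and glucosinolate genes (2.61, adjusted p = 0.032). The other lists did not pass. Among genes with a probe set, those of 2 lists were less often below 11 probes. This comparison splits the same probe numbers at 11, so it is not separate support for the result above. Of the 29 resistance genes 5 (17.2%) had fewer than 11 probes, against 44.9% of the other genes (odds ratio 0.256, Fisher's exact test, adjusted p = 0.0121). Of the 25 cold and drought genes 5 did, also against 44.9% (odds ratio 0.307, Fisher's exact test, adjusted p = 0.0362). Each of these 5 genes had 10 probes. The values were 44.8% for flowering time genes (adjusted p = 1), 25.0% for glucosinolate genes (adjusted p = 0.106) and 31.2% for housekeeping genes (adjusted p = 0.403), which did not pass the same exact test. Genes are not independent replicates, since related genes share sequence, and these lists hold well-studied genes only.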

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

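All alternatives here were chosen after seeing the data; the planned ones (normalization, dim-probe filter, array weights, leaving out arrays and the rest) concern array values and were not run. No paired analysis was possible because the value columns carry no replicate number. The share of nuclear protein-coding genes with a probe set was 40.9% when 11 or more probes were required and 55.9% over all nuclear loci, and differed little with 5 or more probes. The lower share on chromosome 4 (difference of -2.59 percentage points) passed Fisher's exact test and not the rotation test (p = 0.455 before adjustment, adjusted p = 0.972), which keeps neighbouring genes together. The rotation test had little power, as its shifts overlap, so it leaves this difference undecided. No list's odds ratio of having a probe set changed direction. With 11 or more probes required, the ratio passed the test for resistance genes (3.16), glucosinolate genes (2.61) and cold and drought genes (3.62). Against all nuclear loci it passed for resistance and flowering time genes (3.81 each), glucosinolate genes (4.73), cold and drought genes (6.57) and housekeeping genes (4.20), by construction, since that background includes pseudogenes and non-coding loci, few of which have probe sets.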

Other observations

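The test in this part was chosen after the pattern was seen. Several genes of the lists that had no probe set in the table as used were close relatives of each other: MAF2 with MAF3, TGG1 with TGG2, CYP79F1 with CYP79F2, KIN1 with KIN2, and NRG1.1 with NRG1.2. Other related genes of the lists all had probe sets, among them CBF1, CBF2 and CBF3, COR15A and COR15B, AOP1, AOP2 and AOP3, and MAM1 and MAM3. Across the nuclear protein-coding genes, 554 neighbouring pairs shared a symbol stem (such as CYP79F) and 3837 neighbouring pairs with named families did not. Stems were taken from the reference symbols, so not every pair named above counts as same-stem. MAF2 is AGL31 there and shares no stem with MAF3, and NRG1.1 and NRG1.2 have no symbol there and were left out. The same holds for some of the related genes that had probe sets. CBF3 is DREB1A there and shares no stem with CBF1 or CBF2, and MAM3 is IMS2 and shares none with MAM1. AOP2 is not annotated as protein-coding and was left out. Where the first gene of a same-stem pair had no probe set, the second had none in 121 of 175 pairs (69.1%), against a base rate of 30.3% for second genes of such pairs. For pairs of different stems this was 103 of 490 (21.0%), against a base rate of 12.8%. The excess over the base rate was therefore 30.6 percentage points larger for same-stem neighbours (two-sided permutation test over 10000 shuffles of the stem labels, p = 0.0001, the smallest they can give).

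Among these pairs of named families, the difference of 30.6 points argues against missing stretches of rows, whatever the family, as the whole cause. Such stretches would leave out neighbours of different stems as readily, if they fell regardless of where families cluster, which was not examined. Pairs with an unnamed gene were not tested, and the shuffles did not keep neighbouring pairs together, so the p-value may be too small. The difference does not single out a cause that acts on families, because it restates the pattern that prompted it. That probes matching more than 1 near-identical copy were left out, by the array's designers or in the authors' grouping of probes by gene, may be one such cause and stays open, as the sequence identity of the copies was not examined. Shared symbols are only a proxy for relatedness, and neighbouring pairs that share a gene are not independent. No biological explanation was tested, as the number of probes is given for no sample and how the probes were grouped or chosen is not stated.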
